A study of Paralichthys olivaceus with 24 samples.

How the data were processed

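Spleen RNA of Japanese flounder (Paralichthys olivaceus), a marine flatfish, was measured on 24 single-colour (Cy3) Agilent arrays. Fish had received poly(I:C), a synthetic double-stranded RNA used as a stand-in for viral RNA, or DEPC-treated water as the control, and were kept at 15 °C or 25 °C for 3 h or 24 h. The labels give 8 groups of 3 arrays. They do not say that each array held a separate fish, so p-values measure the spread between these samples, which may be partly technical.

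The deposited scanner files hold the intensity of each spot on a linear scale, background-subtracted by Agilent Feature Extraction and not normalised between arrays, per the file headers. The headers give version 10.7.3.1 of that program, whereas the submitters' processing notes give version 9.5.3.1, and the difference was not resolved. The deposited value table holds log2 values by the authors, with the method unstated. Set against the scanner values, its scale and direction were those of the 75th percentile scaling used here, with 100% of values within 0.02 log2 after removal of 1 constant per probe. The centring value of each probe stays unknown. The median of a column of that table ran from -0.16 for replicate 3 of poly(I:C) at 25 °C and 3 h to 0.11 for replicate 3 of water at 25 °C and 24 h.

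Each array held 14661 non-control spots of 14481 probes, of which 14461 had 1 spot and 20 had 10. Spots with outlier marks (2 to 22 per array) and control spots were left out, the log2 signals of a probe's spots were averaged, and the 75th percentile of each array was subtracted. Signals below are log2 values relative to that percentile. A probe was tested if its spots were well above background on all 3 arrays of at least 1 group, which kept 13377 probes and left out 1104. Group means over all 24 arrays were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 16 residual degrees of freedom and a prior of 2.65. Adjusted p-values are limma's with Benjamini-Hochberg adjustment within each comparison, and a probe was called at an adjusted p under 0.05. The 15 comparisons were the poly(I:C) effect in each of the 4 settings, the temperature effect in each treatment and time, the time effect in water at each temperature, and 5 interactions. The comparisons, the naming rule and most alternatives were set before the data were examined.

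The 75th percentile of the processed signal was 348.1 to 863.5 units per array, and 78.4% to 95% of probes were well above background. No array pair held identical values. For the 20 probes with 10 spots, the median SD over the spots of 1 probe was 0.064 log2. The median SD between the arrays of a group was 0.165 for these probes and 0.19 for all tested probes. By group, the median over tested probes was 0.27 in water at 25 °C and 3 h and 0.22 in water at 15 °C and 3 h. In the other groups it lay between 0.16 and 0.20. The fit used 1 spread per probe for all groups, which can understate the error where the 2 water groups at 3 h enter. The number of arrays limits the precision. In data simulated from the measured means and spreads, with 200 of 13377 probes changed for the poly(I:C) effect at 15 °C and 3 h, 93.9% of 4-fold changes, 61.2% of 2-fold changes and 19.4% of 1.5-fold changes were called. For the temperature by poly(I:C) interaction at 3 h, also with 200 probes changed, these shares were 74.2%, 25.4% and 8.96%. In the data 4042 probes were called there. The Benjamini-Hochberg adjustment depends on how many probes change, so the shares hold for the simulated number only.

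The files name each probe's target by a contig code or a database accession and pair none with a gene. Of 14478 distinct target names, 0 matched the NCBI gene table of assembly ASM2471397v2. The 24 gene lists (333 entries) written beforehand were therefore not tested, and genomic positions were not used here. By the rule for this case, at most 2 probes that rose and 2 that fell were named per comparison: those with the largest log2 change among called probes whose replicates did not overlap between the compared groups (for interactions, called only). Where a probe was not well above background on any array of the dimmer group, its fold is a bound, the bright group's mean against, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

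The files place the arrays on 3 slides. Slide 1 held poly(I:C) at 15 °C at both times and 2 arrays of water at 15 °C and 3 h. Slide 2 held water at 15 °C and 24 h, the other array of water at 15 °C and 3 h, poly(I:C) at 25 °C and 3 h, and 1 array of poly(I:C) at 25 °C and 24 h. Slide 3 held water at 25 °C at both times and 2 arrays of poly(I:C) at 25 °C and 24 h. The slide was fitted as a block and as a random block, and 4 comparisons were repeated within 1 slide. The alternatives were quantile and median scaling, normexp background correction, the deposited value table, no filter and a stricter one, another prior, only the compared groups, the replicate number as a block, other thresholds, and each replicate left out. Normexp was to run on mean spot signals. It was run on median spot signals, a choice made after seeing the data, as were the random block and the fits within a slide.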

Results

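The series asked how temperature changes the gene expression response of the flounder spleen to poly(I:C). Spleen expression was measured 3 h and 24 h after poly(I:C) or water at 15 °C and 25 °C, with 3 arrays in each of the 8 groups and 13377 probes tested. Arrays of a group had correlations across probes between 0.963 and 0.989. The first principal component (35.96% of the variance) set poly(I:C) at 25 °C and 3 h (72.6 ± 4.91, SD, n = 3) and poly(I:C) at 15 °C and 24 h (66.6 ± 3.57, SD, n = 3) apart from the other 6 groups, whose means lay between -42.9 and -2.15.

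**Figure D1:**
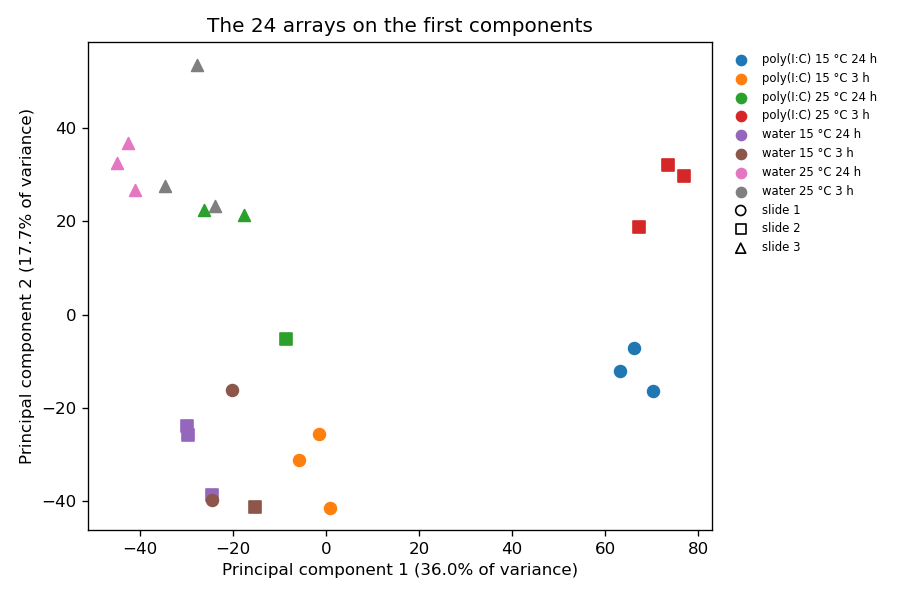
Each point is 1 of the 24 arrays, with principal component 1 on the horizontal axis and component 2 on the vertical axis, coloured by group and shaped by slide. Poly(I:C) at 25 °C and 3 h and poly(I:C) at 15 °C and 24 h both lie on the right of component 1. They lie apart on component 2, at 26.9 ± 7.09 and -11.96 ± 4.64 (SD, n = 3).

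At 15 °C and 3 h, poly(I:C) raised 227 probes and lowered 72, with a median log2 change of 1.49 among those that rose. Probe CUST_7726_PI426483990 (contig JFC06560_1_code) rose from -4.05 ± 0.41 in water to 3.68 ± 0.19 (log2 signal, SD, n = 3), a log2 change of 7.73 (SE 0.42, limma adjusted p = 3.0e-10). Probe CUST_7060_PI426483990 (contig JFC19937_1_code) rose by 6.27 (SE 0.50). Probe CUST_12466_PI426483990 (contig JFC23557_1_code) fell by 1.83 on the log2 scale (SE 0.23). Probe CUST_11286_PI426483990 (contig JFC07148_1_code) was at least 2.58-fold lower, being not well above background on any poly(I:C) array. With normexp 112 probes were called, of which 5 fell, and in a fit of the compared groups alone 139 rose and 19 fell. With the slide as a block 216 probes were called, and among the arrays of slide 1 alone, 3 against 2, 159 were (141 higher and 18 lower). Both settings give the log2 changes without replicate 3 of water, differ only in the estimate of spread, and so are not separate checks.

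At 15 °C and 24 h, 2534 probes rose and 2515 fell, 5049 in all (2428 and 2684 with quantile and 2768 and 2278 with median scaling). Probe CUST_7060_PI426483990 rose from -2.67 ± 0.36 to 5.92 ± 0.62 (log2 signal, SD, n = 3), a log2 change of 8.59 (SE 0.50, limma adjusted p = 1.2e-10). Probe CUST_12833_PI426483990 (contig JFC01040_1_code) was at least 144.7-fold higher than in water, where it was not well above background on any array. Probes CUST_6556_PI426483990 (contig JFC01489_1_code) and CUST_12227_PI426483990 (contig JFC16209_1_code) fell by 5.56 (SE 0.60) and 5.46 (SE 0.42) on the log2 scale. The compared groups lay on different slides, and with the slide as a block 2610 probes were called. The 5049 probes had a median size of 0.89 log2 without the block and 0.94 with it, 99.3% in the same direction, while the median SE of all probes was 0.20 and 0.36.

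At 25 °C and 3 h, 6281 probes were called, of which 2367 rose and 3914 fell. The median change of all probes was -0.15 log2 there, and the balance of directions turned with median scaling, where 3491 rose and 2556 fell, but not with quantile scaling (2761 and 3353) or normexp (1212 and 1391). Probe CUST_377_PI426483993, whose target is a database sequence, was at least 87.8-fold higher than in water, where it was not well above background on any array. Probe CUST_7060_PI426483990 rose by 8.12 (SE 0.50, limma adjusted p = 3.5e-10). Probe CUST_9137_PI426483990 (contig JFC06955_1_code) fell by 4.67 (SE 0.29) on the log2 scale and was well above background on 2 of the 3 poly(I:C) arrays, and probe CUST_5622_PI426483990 (contig JFC18874_1_code) fell by 4.31 (SE 0.32). The groups lay on different slides, and with the slide as a block 2282 probes were called. The median size of the 6281 probes was 0.87 log2 without it and 0.77 with it, 96.6% in the same direction, with a median SE of 0.20 and 0.36.

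At 25 °C and 24 h, 1003 probes rose and 1413 fell, 2416 in all. The median change of all probes was -0.16 log2, and the balance turned with the scaling, to 1287 higher and 841 lower with quantile scaling and to 1301 and 773 with median scaling, as it did with normexp (120 and 96) and at an adjusted p under 0.01 (533 higher of 1000). Probe CUST_7060_PI426483990 was still higher, by 4.30 (SE 0.50, limma adjusted p = 3.9e-05), and probe CUST_12833_PI426483990 by 3.41 (SE 0.40), being well above background on 2 of the 3 water arrays. Probe CUST_6911_PI426483990 (contig JFC08155_1_code) was at least 3.56-fold lower. Probe CUST_10858_PI426483990 (contig JFC12544_1_code) fell by 3.03 (SE 1.03, limma adjusted p = 0.047) and was well above background on 2 of the 3 poly(I:C) arrays, a call lost when any single array of either group was left out. With the slide as a block 1622 probes were called, and within slide 3, 2 arrays against 3, 282 were. Both settings leave replicate 1 of poly(I:C) without weight in the log2 changes, differ only in the estimate of spread, and so are not separate checks. The count was 1451 without replicate 1 and 1577 without replicate 3 of water, and 1578 without replicate 1 and 1495 without replicate 3 of poly(I:C).

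**Figure D2:**
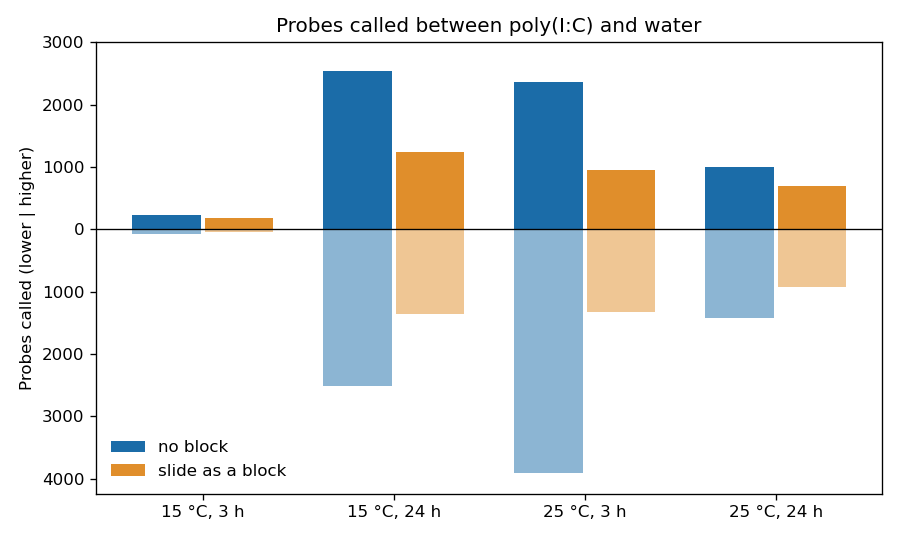
Bars give the number of probes called higher (up, full colour) and lower (down, pale) with poly(I:C) than with water in each of the 4 settings, without a block and with the slide as a block. Without the block 299 probes were called at 15 °C and 3 h, and 6281 at 25 °C and 3 h.

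The 4 responses share no arrays, so their likeness could be compared directly. Across probes, which are not independent replicates, the response at 25 °C and 3 h had a Pearson r of 0.69 (Spearman 0.56) with that at 15 °C and 24 h and of 0.30 (Spearman 0.10) with that at 15 °C and 3 h. The responses at 24 h at both temperatures had an r of 0.34 (Spearman 0.27). Between 3 h and 24 h the r was 0.22 (Spearman 0.02) at 15 °C and 0.36 (Spearman 0.34) at 25 °C. Between 15 °C at 3 h and 25 °C at 24 h it was 0.02 (Spearman -0.09). Of the probes raised at 15 °C and 24 h, 1469 were also raised at 25 °C and 3 h, where independent lists would share 448.4, and 1619 were lowered in both, against 735.9. These 1469 probes had a median log2 change of 0.0013 at 15 °C and 3 h (-0.047 for all probes), and of 0.20 at 25 °C and 24 h (-0.16 for all probes). At 15 °C and 3 h 136 of them were called higher (9.26%) and 9 lower. At 25 °C and 24 h 403 were called higher (27.4%) and 52 lower. Of all tested probes 227 and 1003 were called higher in these settings. Of the 227 probes raised at 15 °C and 3 h, 143 were raised at 15 °C and 24 h (43.0 for independent lists), 183 at 25 °C and 3 h (40.2 for independent lists) and 39 at 25 °C and 24 h (17.02 for independent lists). In all 4 settings 36 probes rose and 4 fell.

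**Figure D3:**
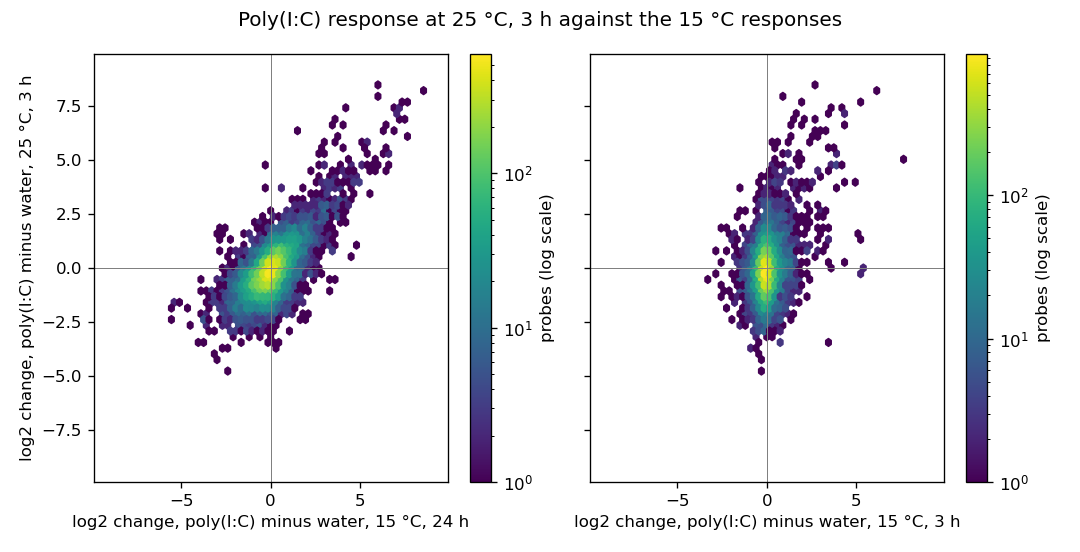
The 13377 probes are binned by their log2 change with poly(I:C) at 25 °C and 3 h (vertical axis) and at 15 °C and 24 h (left) or 3 h (right), with colour for the number of probes on a log scale. The Pearson r was 0.69 on the left and 0.30 on the right.

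The interaction of temperature and poly(I:C) tested whether the response differed between 25 °C and 15 °C. At 3 h it was called for 4042 probes, 1750 more positive and 2292 more negative at 25 °C (2786 and 1279 with median scaling, 2027 and 1830 with quantile scaling, and 651 and 549 with normexp), and 3637 of them were called at 25 °C and not at 15 °C. At 24 h it was called for 3164 probes, 1210 positive and 1954 negative, and quantile scaling turned that balance, to 1551 and 1291, while median scaling (1395 and 1697), normexp (382 and 543) and the slide as a block (459 and 765) did not. The median interaction of all probes was -0.12 log2 at 3 h and -0.13 log2 at 24 h. At both times 1489 probes were called, and 1335 of these had opposite signs at 3 h and 24 h. Probe CUST_11992_PI426483990 (contig JFC28148_1_code) reached 1.80 ± 1.19 with poly(I:C) at 25 °C and 3 h and 0.014 ± 1.08 at 15 °C and 24 h (log2 signal, SD, n = 3). It was not well above background on any poly(I:C) array at 15 °C and 3 h or at 25 °C and 24 h. Probe CUST_6587_PI426483990 (contig JFC00244_1_code) had an interaction of -8.60 at 24 h (SE 1.11, limma adjusted p = 1.5e-05), a size that was not fully measured, as the probe was not well above background on any water array at 15 °C and 24 h. With the slide as a block the interaction was called for 1155 probes at 3 h and 1224 at 24 h. Probes called without the block had median sizes of 1.08 at 3 h and 1.17 at 24 h without it, and of 0.93 and 1.10 with it, 98.4% and 99.7% in the same direction, while the median SE rose from 0.28 to 0.42 at both times.

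The change of the poly(I:C) response from 3 h to 24 h was called for 3652 probes at 15 °C (3041 with the slide as a block) and 3447 at 25 °C (2224 with it, the median size being 1.06 without the block and 1.02 with it and the median SE 0.28 and 0.34). At 25 °C 1696 were positive and 1751 negative, with 1301 and 2158 under median and 1805 and 1495 under quantile scaling. At 15 °C, probes CUST_7933_PI426483990 (contig JFC02466_1_code) and CUST_294_PI426483993 had interactions of -6.37 (SE 0.34) and -6.33 (SE 0.35). Their log2 changes with poly(I:C) were 5.19 and 5.20 at 3 h, and -1.18 and -1.13 at 24 h, where both were called lower than in water. Whether both probes read the same transcript was not tested. At 25 °C, probe CUST_9137_PI426483990 had an interaction of 4.98 (SE 0.41, limma adjusted p = 7.8e-08) and was well above background on 2 of the 3 poly(I:C) arrays at 3 h. The difference of this change between temperatures was called for 4462 probes, 2157 positive and 2305 negative (1699 and 2922 with median and 2209 and 2136 with quantile scaling), and for 3187 with the slide as a block.

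**Figure D4:**
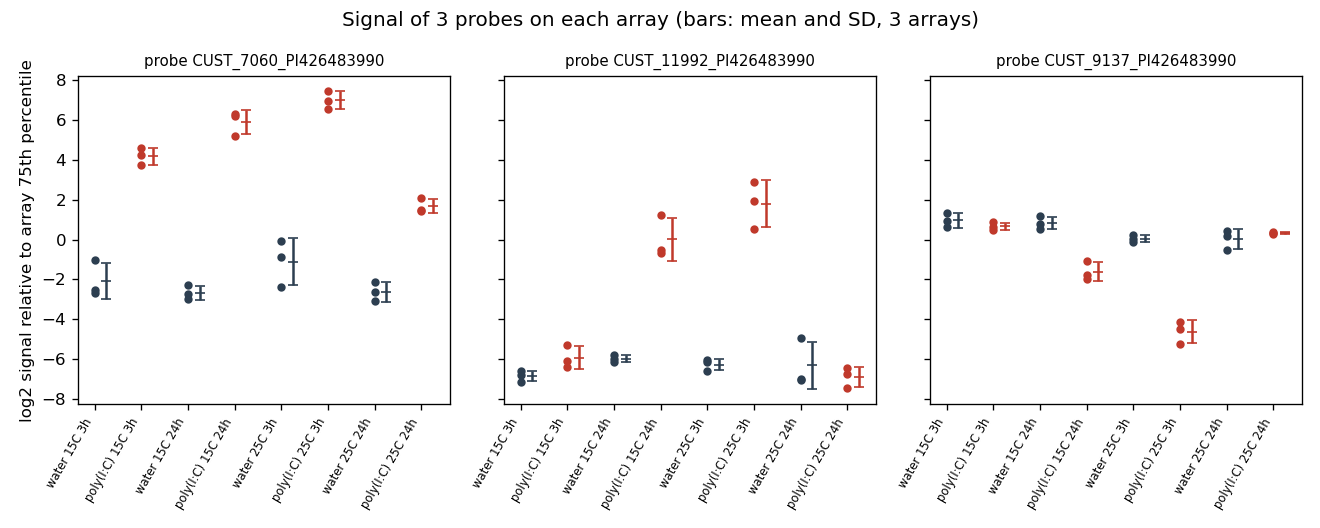
Points give the log2 signal relative to the array's 75th percentile on each array for 3 probes, by group (red for poly(I:C), dark blue for water), with the mean and SD beside them (n = 3). The signal of CUST_7060_PI426483990 was 5.92 with poly(I:C) at 15 °C and 24 h and 1.67 at 25 °C and 24 h.

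Between 25 °C and 15 °C in water, 3676 probes were called at 3 h (1873 higher and 1803 lower at 25 °C) and 3738 at 24 h (2346 higher, 1862 of 3763 with quantile scaling, and 2134 of 3642 with median scaling). The balance at 3 h turned to 1791 higher and 2349 lower with quantile scaling and to 1623 and 2181 with median scaling, while of the changes of at least 2-fold 889 were higher and 345 lower (969 and 249 at 24 h). A fit of the compared groups alone called 1066 probes at 3 h (631 higher and 435 lower), and normexp gave 834 at 3 h (458 and 376) and 741 at 24 h (447 and 294). At 3 h probe CUST_184_PI426483990 (contig JFC24126_1_code) was at least 19.6-fold higher at 25 °C, and probe CUST_10148_PI426483990 (contig JFC14084_1_code) fell by 2.51 (SE 0.22, limma adjusted p = 6.5e-07). At 24 h probe CUST_12416_PI426483990 (contig JFC17017_1_code) was higher by 3.72 (SE 0.49) and probe CUST_12995_PI426483990 (contig JFC17102_1_code) fell by 3.43 (SE 0.54). All water arrays at 25 °C lay on slide 3 and none at 15 °C did. With the slide as a block 83 probes were called at 3 h and 214 at 24 h, and no slide held both groups. That block rests on 2 groups that bridge slides, with 1 array against 2 in each, and the median SE rose with it from 0.20 to 0.41 at 3 h and to 0.36 at 24 h. The named changes at 24 h and that of CUST_184_PI426483990 were no longer called with it, at 2.56 (SE 0.85) for CUST_12416_PI426483990, -3.32 (SE 0.93) for CUST_12995_PI426483990, and 1.94 (SE 1.51) against 4.76 (SE 0.80) without it for CUST_184_PI426483990.

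In poly(I:C) fish, 6312 probes differed between temperatures at 3 h, 2724 of them higher at 25 °C (3915 of 6447 with median and 2830 of 6064 with quantile scaling), and 5619 at 24 h, 2581 higher and 3038 lower (2937 and 2792 with quantile scaling, 1405 and 1155 with normexp, and 2784 and 2830 with median scaling). At 3 h probe CUST_11992_PI426483990 was at least 78.6-fold higher and probe CUST_9137_PI426483990 fell by 5.30 (SE 0.29, limma adjusted p = 1.3e-10). At 24 h probe CUST_7579_PI426483990 (contig JFC21892_1_code) was higher by 5.10 (SE 0.22), and probe CUST_11992_PI426483990 was at least 34.9-fold lower. All poly(I:C) arrays at 15 °C lay on slide 1 and none at 25 °C did. The calls without a block may therefore hold slide differences as well as temperature, as in water. With the slide as a block the counts were 2819 and 1476. Probes called without it had median sizes of 0.88 at 3 h and 0.87 at 24 h without the block, and of 0.83 and 0.79 with it, 98.6% and 96.9% in the same direction, and the median SE rose from 0.20 to 0.36 and 0.41.

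Between 24 h and 3 h in water, 123 probes were called at 15 °C, 9 higher and 114 lower (20 and 68 with the slide as a block), and 1024 at 25 °C, 599 higher and 425 lower (57 and 70 with normexp). Probe CUST_12932_PI426483990 (contig JFC06162_1_code) fell by 4.25 (SE 0.35, limma adjusted p = 3.5e-06) at 15 °C, and probe CUST_6259_PI426483990 (contig JFC12526_1_code) by 5.29 (SE 0.56, limma adjusted p = 4.2e-05) at 25 °C. At 15 °C the count was 69 without replicate 2 and 65 without replicate 3 of the 24 h group, and 262 (135 higher and 127 lower) without replicate 1 and 63 without replicate 3 of the 3 h group. At 25 °C it was 651 without replicate 2 of the 24 h group and 584 without replicate 3 of the 3 h group. A limma fit of the compared groups alone called 41 probes at 15 °C and 0 at 25 °C, where 1871 had an unadjusted p under 0.05.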

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

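The tests of slide and of noise below were chosen after related values had been seen. The test of scaling and the counts of other splits were set beforehand, but the counts for the interactions were corrected after a first version, which took a split and its mirror as 2, had been seen.

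The poly(I:C) response differed between temperatures or times in 5 interaction tests, with 4042 probes (3 h) and 3164 (24 h) for temperature, 3652 (15 °C) and 3447 (25 °C) for time, and 4462 for all 3 factors. Labels of temperature or time were exchanged within treatment in 100 splits each, the real one included. As many probes were called in 1 split for time at 15 °C (highest other 3589) and 1 for the 3 factors (highest other 3312). The first version gave 3 (highest other 3837) and 1 (highest other 4412). For temperature at 24 h 4 splits did (highest other 3716), and 6 in the first version. For temperature at 3 h 5 splits did (highest other 5098) in both versions. For time at 25 °C 8 did (highest other 5067), and 7 (highest other 4319) in the first version. In the splits with the highest other counts at least 1 treatment kept or fully exchanged its real groups, so these counts hold the effect of temperature or time itself, a structure of the samples. Exchanging labels within treatment breaks that effect along with the interaction. The splits therefore cannot decide on chance for an interaction, and no conclusion is drawn from them.

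The 2-group comparisons allow 10 splits each, too few for a share under 0.05. The real count and the highest other were 299 and 130, 5049 and 0, 6281 and 10, and 2416 and 0 for poly(I:C) at 15 °C (3 h, 24 h) and 25 °C (3 h, 24 h). They were 3676 and 239, and 3738 and 0, for temperature in water, and 6312 and 1, and 5619 and 2, for temperature in poly(I:C). For time in water they were 123 and 256 at 15 °C, where 2 splits reached the real count, and 1024 and 34 at 25 °C, while in the other 9 comparisons 1 split did.

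Named probes differed as follows. For temperature at 3 h the interactions were 7.16 (CUST_11992_PI426483990), 5.77 (CUST_377_PI426483993), -6.87 (CUST_3444_PI426483990) and -5.44 (CUST_7260_PI426483990). At 24 h they were 4.83 (CUST_6556_PI426483990), 4.62 (CUST_5405_PI426483990), -8.60 (CUST_6587_PI426483990) and -7.50 (CUST_13312_PI426483990). For time at 15 °C they were 6.38 (CUST_6259_PI426483990), 6.11 (CUST_12677_PI426483990), -6.37 (CUST_7933_PI426483990) and -6.33 (CUST_294_PI426483993). The value of CUST_12677_PI426483990 had an SE of 1.83. Its water arrays at 15 °C ranged from -6.58 to -1.34 at 24 h and from -7.03 to -1.39 at 3 h (log2 signal). For time at 25 °C they were 4.98 (CUST_9137_PI426483990), 3.98 (CUST_5979_PI426483990), -8.66 (CUST_11992_PI426483990) and -8.12 (CUST_6587_PI426483990). For the 3 factors they were 7.86 (CUST_6001_PI426483990), 7.12 (CUST_9137_PI426483990), -13.73 (CUST_11992_PI426483990) and -13.53 (CUST_6587_PI426483990). In at least 1 group that enters the interaction named, CUST_11992_PI426483990, CUST_377_PI426483993, CUST_3444_PI426483990, CUST_6587_PI426483990 (at 24 h and for the 3 factors), CUST_13312_PI426483990, CUST_12677_PI426483990 and CUST_5979_PI426483990 were not well above background on any array, so these sizes are neither fully measured nor bounds.

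The response at 25 °C and 3 h was more like that at 15 °C and 24 h than that at 15 °C and 3 h. Both of the similar responses compare different slides, but the 24 h minus 3 h change in poly(I:C) at 15 °C, with all 6 arrays on slide 1, had an r of 0.51 with the response at 25 °C and 3 h (0.49 to 0.52 with 1 array left out), which argues against slides as the whole cause. The r with 15 °C and 24 h exceeded that with 15 °C and 3 h by 0.41 under quantile scaling, and by 0.37 after the variance from noise was taken out, against scaling and noise as the cause. A slide part stays open, as the slide 2 minus slide 3 difference inside poly(I:C) at 25 °C and 24 h had an r of 0.26 with the response at 25 °C and 3 h. That the response may run earlier at 25 °C is a hypothesis found on these same data, and its timing was not tested.

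Calls for temperature in water fell from 3676 to 83 (3 h) and from 3738 to 214 (24 h) with the slide as a block, which rests on 2 groups that bridge slides, 1 array against 2 in each. The median SE rose with it from 0.20 to 0.41 and 0.36, so the fall in calls holds lost precision. Probes called without it kept their direction in 96.0% and 96.8% of cases, at median sizes of 0.63 (0.78 without) and 0.60 (0.77 without). These probes were chosen by their calls on the same arrays, so the sizes cannot tell whether the changes themselves are smaller. The slide 3 minus slide 2 difference inside poly(I:C) at 25 °C and 24 h, where temperature is constant, had an r of 0.46 with the temperature change in water at 3 h and of 0.36 at 24 h. The 9 differences of 1 against 2 arrays inside poly(I:C) groups on 1 slide reached at most 0.27 and 0.15 in size, and water groups were not used for these. Slide differences may therefore account for part of these calls. The slides of this difference match those of the change at 24 h only. At 3 h, 2 of the 3 water arrays at 15 °C lay on slide 1. The larger r thus lies where the slides match less, so the r at 3 h is weaker ground for slides. The slide 3 minus slide 2 difference rests on 1 array of slide 2, and temperature itself remains open, since no slide held both water groups of either time. The slide block takes its step from slide 2 to slide 3 from that same difference. The fall in calls and these r values are therefore not separate evidence. The slide 2 minus slide 1 difference inside water at 15 °C and 3 h had an r of -0.15 with the change at 24 h. That change compares slides 3 and 2, so this r cannot decide for or against slides.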

How the results depend on the processing

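Normexp on median signals, the random slide block, the fits within 1 slide and all but the quantile, value table and stricter filter settings of the correlations were chosen after seeing the data. Of 199 counts under an alternative, 141 lay within 1.5 times the reported one, and of 132 counts with 1 array left out, 122 did. Counts beyond 1.5 times follow, and the cause was not tested unless given. With normexp they were 112 (poly(I:C) at 15 °C and 3 h), 2216 (poly(I:C) at 15 °C and 24 h), 2603 (poly(I:C) at 25 °C and 3 h), 216 (poly(I:C) at 25 °C and 24 h), 834 (temperature in water at 3 h), 741 (temperature in water at 24 h), 2732 (temperature in poly(I:C) at 3 h), 2560 (temperature in poly(I:C) at 24 h), 1200 (temperature by poly(I:C) at 3 h), 925 (temperature by poly(I:C) at 24 h), 1224 (time by poly(I:C) at 15 °C), 977 (time by poly(I:C) at 25 °C), 15 (time in water at 15 °C), 127 (time in water at 25 °C) and 1666 (the 3 factors). With the slide as a block they were 2610 (poly(I:C) at 15 °C and 24 h), 2282 (poly(I:C) at 25 °C and 3 h), 83 (temperature in water at 3 h), 214 (temperature in water at 24 h), 2819 (temperature in poly(I:C) at 3 h), 1476 (temperature in poly(I:C) at 24 h), 1155 (temperature by poly(I:C) at 3 h), 1224 (temperature by poly(I:C) at 24 h) and 2224 (time by poly(I:C) at 25 °C), while the random slide block (correlation 0.056) moved none beyond 1.5 times. That correlation rests on the 2 groups that bridge slides, so the random block cannot weigh for or against slides. Within 1 slide, with fewer arrays, they were 159 (poly(I:C) at 15 °C and 3 h), 282 (poly(I:C) at 25 °C and 24 h), 30 (time in water at 15 °C) and 112 (time in water at 25 °C). With only the compared groups, which leaves fewer degrees of freedom and takes the spread from these groups alone (effects not told apart), the counts beyond 1.5 times were 158 (poly(I:C) at 15 °C and 3 h), 1188 (poly(I:C) at 25 °C and 24 h), 1066 (temperature in water at 3 h), 41 (time in water at 15 °C) and 0 (time in water at 25 °C). With at least 2-fold added, which can only lower a count, they were 182 (poly(I:C) at 15 °C and 3 h), 2150 (poly(I:C) at 15 °C and 24 h), 2560 (poly(I:C) at 25 °C and 3 h), 538 (poly(I:C) at 25 °C and 24 h), 1234 (temperature in water at 3 h), 1218 (temperature in water at 24 h), 2577 (temperature in poly(I:C) at 3 h), 2276 (temperature in poly(I:C) at 24 h), 2266 (temperature by poly(I:C) at 3 h), 1992 (temperature by poly(I:C) at 24 h), 2159 (time by poly(I:C) at 15 °C), 1868 (time by poly(I:C) at 25 °C), 71 (time in water at 15 °C) and 224 (time in water at 25 °C). With an adjusted p under 0.01, likewise, they were 190 (poly(I:C) at 15 °C and 3 h), 1000 (poly(I:C) at 25 °C and 24 h), 2020 (temperature in water at 3 h), 2027 (temperature in water at 24 h), 2328 (temperature by poly(I:C) at 3 h), 1774 (temperature by poly(I:C) at 24 h), 2228 (time by poly(I:C) at 15 °C), 2078 (time by poly(I:C) at 25 °C), 44 (time in water at 15 °C), 394 (time in water at 25 °C) and 2915 (the 3 factors). With 1 array left out, the counts ran from 1451 to 2076 for poly(I:C) at 25 °C and 24 h, from 63 to 262 for time in water at 15 °C, and from 584 to 1454 for time in water at 25 °C. The value table equals the scaled values up to a constant per probe, so it could move almost nothing. The correlation of responses at 24 h moved from 0.34 to 0.44 with normexp and 0.45 with the stricter filter. Of 1092 values of named probes under alternatives, 1047 stayed called, 45 were no longer called (10 with the slide as a block, 12 with normexp, 13 with 1 array left out) and 0 changed sign, and 36 more were not computed, as the stricter filter left the probe out. Same-numbered arrays had a mean correlation of deviations of -0.00068 (0.00046 for other numbers), 10 of 24 arrays correlated best with their own number, and every same-number correlation was over 0.1 in 1 comparison, temperature in water at 3 h, where the replicate block called 3545 probes. The replicate block moved no count beyond 1.5 times. Gene list shifts and their alternatives, and normexp on mean signals, were not run. Signal over background limits dim probes: 10418 of 13377 were well above background on all 24 arrays.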

Other observations

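The test here was set before its result was seen, but after the probe names were known. Probes whose target is a database sequence (337 tested) were compared with contig probes, as a hypothesis that sequences studied one by one rise more often with poly(I:C). At 15 °C and 3 h 24 of them (7.12%) rose, against 1.56% of contig probes, and none of 10000 random sets of contig probes matched on mean signal had as high a share (percentile 100, highest 5.04%), so brightness does not account for it. At 15 °C and 24 h (percentile 87.3), 25 °C and 3 h (54.4) and 25 °C and 24 h (10.04) the shares lay within those of the matched sets. The shares that fell were not tested against matched sets: 0.30% against 0.54% of contig probes and 27.9% against 18.6% at 15 °C (3 h, 24 h), and 23.4% against 29.4% and 18.1% against 10.4% at 25 °C. Several probes may stand for 1 gene, which was not tested and could widen the spread of such shares.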
